A study of Arabidopsis thaliana with 8 samples.

How the data were processed

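Rosette leaves of 2 genotypes of Arabidopsis thaliana were compared on Affymetrix arrays, with 4 arrays per group and 8 in all, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted from ground frozen leaves and biotin-labelled cDNA was hybridised. The authors deposited expression values made with RMA, per the submitters' processing notes; RMA subtracts background, normalizes arrays to a common distribution and summarises probes on a log scale. The RMA version, the chip definition, the genome build and the log base are not given in the sources used here, and the values, from 0.69 to 13.7, were taken as log2 because RMA gives that scale. The table held 27826 loci named by locus identifier, of which 27720 were nuclear, 14 plastid and 92 mitochondrial, with 1 value per locus and array and no missing value. All 8 arrays held the same sorted values, with a median of 2.73, so the table had been quantile-normalized. A global rise or fall of all transcripts therefore cannot be seen in it, and values of closely related genes depend on probes whose specificity was not examined here. RNA quality, scan dates and slides were not analysed here, so a batch that coincides with the groups cannot be told apart from them.

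Locus identifiers were matched to the gene table of the TAIR10.1 assembly for symbols and for which loci are neighbours, and 27241 matched while 585 did not. NAA50 and some other acetyltransferase genes carry the names of the field's nomenclature. No coordinates are printed, since the build behind the array's probe sets is not given in the sources used here.

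From the deposited values, taken as log2, a linear model with the group as its only term was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with lmFit and eBayes and no filter on dim loci. Differences are the arrays labelled NAA50-depleted minus wild type, with the moderated standard error, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over all 27826 loci, with a threshold of 0.05. Genes were also counted at a change of at least 2-fold and at least 4-fold. The 32 gene lists, 23 of functions and 9 of leaf cell types or other organs, were tested with camera at a preset correlation between genes of 0.01, adjusted over all lists, and a list was called at an adjusted p under 0.05. Camera was repeated with the correlation estimated for each list, under which 0 of the 13 called lists (6 up and 7 down) passed. Fry, which tests whether a list's own genes move one way without comparing them with other genes, called 10 lists. Members were counted past an adjusted p of 0.05 over all genes and adjusted over the list alone. Of the listed genes 638 were used, 2 were left out because their symbol belonged to another locus and 1 was not measured.

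The groups, tests, gene lists, alternatives and rule for named genes were fixed before the data were examined. The rule took the 9 largest increases and 9 largest decreases past the threshold whose groups did not overlap, then NAA50, NAA10, NAA15 and HYPK, and from each list the 2 largest increases and 2 largest decreases past the threshold, or the member with the largest change where none passed. Further members given beside these were chosen after their values were seen: WRKY33, BAK1, RBOHD, ICS1, LOX4, WRKY53, IRE1A, ERO1, MYB28, CYP83A1, CHLH, RBCS2B, RBCS1A, IAA5, PIN7, CCA1 and LHY.

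The alternatives were the replicate number as a block, quantile normalization, median centring, cyclic loess normalization, a filter that kept loci above the 25th percentile on at least 4 arrays, a trended and robust variance model, array weights, each array left out in turn, an adjusted p of 0.01, a test against a log2 change of 0.25 with treat, the estimated correlation and fry. The fit was tested on simulated data with the real loci and spread, in which 6 of 121 calls were false. The changed loci were drawn only from those with a mean above 3, so recovery at dimmer loci was not tested. List tests were tested on simulated lists whose genes also had a mean above 3 and were drawn independently of each other. That test therefore does not cover the correlation between genes that was estimated in the real lists. All 35 distinct splits of the 8 arrays into 4 and 4 were fitted to count the genes they call. Single arrays far from the other 3 of their group were sought with Dixon's ratio, for which chance marks about 1 in 20 groups.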

Results

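Transcript levels in rosette leaves of Arabidopsis thaliana were measured on 8 Affymetrix arrays. Wild type plants of the Col-0 accession gave 4 arrays, and a line that the labels describe as depleted in NAA50 steady-state level gave the other 4. NAA50 is an N-terminal acetyltransferase, an enzyme that acetylates the first residue of proteins. All plants were 7 weeks old, and the leaves were frozen 2 h after the lights came on. The table held 1 expression value, taken as log2, for each of 27826 loci, and the number of arrays limits the precision of every value. Pearson correlations across loci were 0.979 to 0.988 between arrays of one group and 0.951 to 0.967 between arrays of different groups. The first principal component held 54.6% of the variance and separated the groups. On the second, with 10.7%, labelled-depleted replicate 3 lay at 34.7, replicate 4 at -29.9 and wild type replicate 1 at 20.7. The labels do not say that the arrays came from separate plants, so p-values measure only the spread between these arrays.

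The comparison asked which transcripts differ between the leaves labelled NAA50-depleted and wild type leaves, and the targeted gene was examined first. NAA50 (AT5G11340) was higher, not lower, on the arrays labelled NAA50-depleted. Its log2 values on the wild type arrays were 4.71, 4.54, 4.23 and 4.75, and on the arrays labelled depleted they were 10.43, 10.52, 10.24 and 10.33. The difference was 5.83 ± 0.14 on the log2 scale (SE, n = 4 arrays per group), or 56.7-fold, with an adjusted p of 3.47e-09 in limma. NAA50 lay between percentiles 66.8 and 73.0 of all loci on the wild type arrays and between 99.5 and 99.6 on the arrays labelled depleted. The sample titles give a depleted NAA50 steady-state level and do not say whether of transcript or protein. If transcript is meant, the measured level went against the group label. Every direction given here is that of the arrays labelled NAA50-depleted relative to those labelled wild type. Where the probes lie on the transcript is not given in the sources used here, so this value checks the label only for the part of the transcript that was probed.

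**Figure D1:**
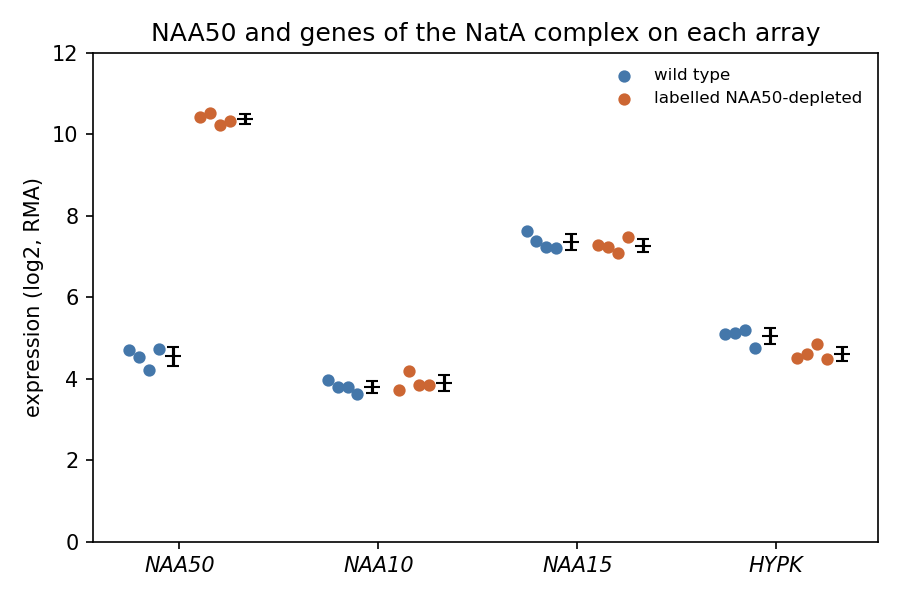
Expression on the log2 scale (vertical axis) of NAA50, NAA10, NAA15 and HYPK (horizontal axis) on each of the 4 wild type arrays (blue) and the 4 arrays labelled NAA50-depleted (orange), with a black bar at each group's mean and whiskers of 1 SD. NAA50 lies between 4.23 and 4.75 on the wild type arrays and between 10.24 and 10.52 on the arrays labelled depleted, while for the other genes the groups differ by 0.44 or less.

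The subunits of NatA, the ribosome-bound acetyltransferase complex with which NAA50 associates, did not pass the threshold. NAA10, the catalytic subunit, differed by 0.09 ± 0.13 (SE, n = 4 arrays per group, adjusted p = 0.740), and NAA15, the auxiliary subunit, by -0.09 ± 0.13 (adjusted p = 0.742). NAA10 was 0.15 after cyclic loess and without wild type replicate 1 or labelled-depleted replicate 1, 0.04 without wild type replicate 4 and -0.004 without labelled-depleted replicate 2. NAA15 was 0.03 after cyclic loess, -0.01 and -0.14 without wild type replicates 1 and 4, and -0.03 and -0.16 without labelled-depleted replicates 3 and 4. HYPK, a NatA-binding protein, differed by -0.44 ± 0.14 (adjusted p = 0.0533), and it passed without wild type replicate 4 (-0.53), without labelled-depleted replicate 3 (-0.52) and with a filter on dim loci (-0.44). Among the 18 N-terminal acetyltransferase genes, NAA50 and NAA60 (0.65 ± 0.19) rose and GNAT10 (-1.10 ± 0.14) and GNAT3 (-0.68 ± 0.20) fell over all genes, while 2 rose and 3 fell adjusted over the list alone. The median of that list was -0.05, its mean 0.20 and its camera direction down, with an adjusted p of 0.887. The call of NAA60 was lost without wild type replicate 2, 3 or 4 or labelled-depleted replicate 1, 2 or 4, at 0.51 to 0.72. The call of GNAT3 was lost without wild type replicate 2 or any single array labelled depleted, at -0.73 to -0.65, and after cyclic loess, at -0.61, and its value was -0.45 without wild type replicate 1.

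Of the 27826 loci, 4042 (14.5%) differed between the groups at an adjusted p under 0.05 in limma, 1934 of them higher and 2108 lower on the arrays labelled NAA50-depleted. These are 6.95% and 7.58% of all loci, while among loci with a mean above 4 the shares were 13.0% and 15.6%. Counts of list members given below stand against these shares. The larger changes were mostly increases, with 889 genes at least 2-fold higher and 437 at least 2-fold lower, and 237 and 31 genes at 4-fold. The array median was 2.73 and the lowest value 0.69, so dim loci had less room to fall than to rise. How far this adds to the excess of increases was not tested. The groups did not overlap at 5244 loci (18.8%), where chance gives 2.86%. After cyclic loess normalization 2267 genes were higher and 1559 lower, so that the share of higher genes among those changed was 59.3% in place of 47.8%. Simulated data with the same number of loci held far fewer changes, with 67, 67 and 66 loci changed by 0.5, 1 and 2 on the log2 scale. Of these 14.9%, 61.2% and 97.0% were recovered. The adjustment is stricter where fewer genes change, so these shares do not give the recovery in the real data. The changed loci were not drawn from the dim end of the arrays, so the shares do not cover it.

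BT2, a BTB and TAZ domain protein, showed the largest increase of all genes called, at 7.38 ± 0.32 on the log2 scale (SE, n = 4 arrays per group) or 167-fold (adjusted p = 7.99e-07). Its wild type values, 2.21 to 3.91, lay near the array median of 2.73, where signal over background was not shown, so the size of the fold is less certain than its direction. After NAA50 came DIN10, a dark-inducible gene of the raffinose synthase family, at 5.79 ± 0.42, and XTH22, the touch-inducible xyloglucan endotransglucosylase also called TCH4, at 5.54 ± 0.26. PUB23, a U-box ubiquitin ligase of immune signalling, rose by 4.67 ± 0.23, the lipase PLA2A by 4.63 ± 0.22, the abscisic acid receptor PYL5 by 4.35 ± 0.26, AT1G02610 by 4.27 ± 0.20 and the ERF-family transcription factor DREB26 by 4.22 ± 0.33. Their adjusted p-values in limma were at most 1.52e-05. The wild type means of DIN10 (3.06), PYL5 (3.40), XTH22 (3.48) and AT1G02610 (3.70) also lay near the array median. The sizes of these increases are likewise less certain. XTH31, a xyloglucan-modifying enzyme, showed the largest decrease, at -4.79 ± 0.27 or 27.7-fold (adjusted p = 1.93e-06). The endoglucanase GH9C2 (-3.20 ± 0.17), AT3G55240 (-3.03 ± 0.41), the auxin-response repressor IAA29 (-2.90 ± 0.40) and AT5G01790 (-2.70 ± 0.21) also fell. So did the rubredoxin-family gene ENH1 (-2.58 ± 0.25), AT5G24155 (-2.53 ± 0.42), AT5G51010 (-2.50 ± 0.27) and the growth-related SAUR21 (-2.45 ± 0.23). For these decreases the adjusted p was at most 0.00191. The labelled-depleted means of XTH31 (3.10), ENH1 (2.98), AT5G51010, IAA29 and AT5G01790 lay near the array median of 2.73. The sizes of the decreases of these genes, including the 27.7-fold of XTH31, are likewise less certain.

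Of the genes of pattern-triggered immunity, the response to microbial molecules, 12 of 23 measured members rose on the arrays labelled NAA50-depleted and none fell. WRKY22, a transcription factor of this pathway, rose by 3.63 ± 0.23 on the log2 scale (SE, n = 4 arrays per group) and the PHOSPHATE-INDUCED gene PHI1 by 3.48 ± 0.20, the former from a wild type mean of 2.36 and the latter from wild type values of 1.12 to 1.74. These lay below the array median of 2.73, so both sizes are less certain. WRKY33 rose by 2.62 ± 0.21, the co-receptor BAK1 by 0.97 ± 0.17 and the NADPH oxidase RBOHD by 1.06 ± 0.21. These counts are over all genes, while 15 rose adjusted over the list alone. The median member differed by 0.91 and the camera adjusted p was 1.83e-12, with an adjusted p = 0.178 with an estimated correlation. The epidermis and cuticle markers described further on had a median of -0.48 on the same arrays, a fact that stands beside each of the other 12 called lists.

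Of the salicylic acid defence genes, WRKY18 rose by 3.73 ± 0.17 (SE, n = 4 arrays per group) and CBP60G, a transcriptional activator of salicylic acid synthesis, by 1.81 ± 0.21. The synthesis enzyme ICS1 rose by 0.56 ± 0.17. Over all genes 10 of 30 members rose and none fell, against 13 and 1 adjusted over the list alone. The median was 0.60 (camera adjusted p = 1.16e-06), with an adjusted p = 0.489 with an estimated correlation. Without labelled-depleted replicate 1 the median was 0.36 and the list was still called. The count of members that rose was 5 without wild type replicate 4 or labelled-depleted replicate 1, and 6 without wild type replicate 1 or 3 or labelled-depleted replicate 2.

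Jasmonate and ethylene response genes had a median difference of 0.64. PDF1.2, a plant defensin, rose by 3.59 ± 0.48 and the jasmonate repressor gene JAZ7 by 2.59 ± 0.27 (SE, n = 4 arrays per group), the latter from a wild type mean of 1.79 below the array median of 2.73. The lipoxygenase LOX4 rose by 2.08 ± 0.32. Over all genes 9 of 28 members rose, 12 adjusted over the list alone, and none fell in either count. The camera adjusted p was 2.81e-05, with an adjusted p = 0.695 with an estimated correlation. The list was not called with fry (adjusted p = 0.187), and the median was 0.32 without labelled-depleted replicate 3.

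Among leaf senescence genes, increases outnumbered decreases, while most members did not pass the threshold. BCB, a blue copper protein, rose by 3.61 ± 0.23, SAG21 by 2.73 ± 0.22 and the transcription factor WRKY53 by 2.66 ± 0.18 (SE, n = 4 arrays per group). NYC1, a chlorophyll b reductase, fell by 1.61 ± 0.30. Its labelled-depleted mean of 2.98 lay near the array median of 2.73, so the size of that fall is less certain. Over all genes, and also adjusted over the list alone, 6 of 18 members rose and 1 fell. SEN1 and ASN1, among those that rose over all genes, are counted again below among genes of darkness and carbon starvation. The median was 0.28 (camera adjusted p = 0.000311), with an adjusted p = 0.258 with an estimated correlation. Without labelled-depleted replicate 2 the median was 0.10.

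Autophagy genes shifted slightly upward. ATG8E, a ubiquitin-like protein of the autophagosome membrane, rose by 1.88 ± 0.13 and ATG2 by 0.72 ± 0.16 (SE, n = 4 arrays per group). Over all genes 4 of 22 members rose, 6 adjusted over the list alone, and none fell, where 13.0% of all genes with a mean above 4 were higher. The median was 0.09 (camera adjusted p = 0.00696), with an adjusted p = 0.489 with an estimated correlation. It was 0.15 without wild type replicate 2, 0.06 without wild type replicate 4 and 0.16 after cyclic loess, and without wild type replicate 1 the count over all genes was 2.

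Of the genes for stress and protein folding in the endoplasmic reticulum (ER), the membrane-tethered transcription factor NAC062 rose by 1.42 ± 0.18 (SE, n = 4 arrays per group) and BZIP60, a transcription factor of the unfolded protein response, by 2.30-fold (95% interval 1.70 to 3.10). The splicing kinase IRE1A rose by 0.58 ± 0.12 and the oxidoreductase ERO1 by 0.94 ± 0.21. These were the only members called, 4 of 27 both over all genes and adjusted over the list alone. That is near the 13.0% that were higher among all genes with a mean above 4. The list median was 0.16 (camera adjusted p = 0.0144), with an adjusted p = 0.850 with an estimated correlation. It was not called with fry (adjusted p = 0.416). The call rested on labelled-depleted replicate 1, without which the median turned to -0.08 (adjusted p = 0.916). The median was 0.31 without wild type replicate 3, 0.26 without labelled-depleted replicate 3 or 4, and 0.28 after cyclic loess.

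Of the genes of aliphatic glucosinolate synthesis, which makes methionine-derived defence compounds, both regulators and enzymes were among those that fell on the arrays labelled NAA50-depleted. The transcription factors MYB29 and MYB28 differed by -1.96 ± 0.20 and -1.78 ± 0.18 on the log2 scale (SE, n = 4 arrays per group), the S-oxygenase FMOGS-OX3 by -1.78 ± 0.19 and the cytochrome P450 CYP83A1 by -1.14 ± 0.16. Over all genes 13 of 19 measured members fell and none rose, while 16 fell adjusted over the list alone. The median was -0.90 (camera adjusted p = 9.42e-12), with an adjusted p = 0.489 with an estimated correlation. The median of the epidermis and cuticle markers was -0.48 on the same arrays.

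Of the chlorophyll synthesis genes, HEMA1, the glutamyl-tRNA reductase at the start of the pathway, changed by -2.44 ± 0.32, the vinyl reductase DVR by -1.03 ± 0.18 and the magnesium chelatase subunit CHLH by -0.98 ± 0.15 (SE, n = 4 arrays per group). In both counts, over all genes and adjusted over the list alone, 8 of 13 members fell and none rose. The median was -0.51 (camera adjusted p = 0.000183), with an adjusted p = 0.574 with an estimated correlation. Beside it the epidermis median was -0.48.

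Of the nuclear genes of photosynthesis, RBCS1B, a small subunit of Rubisco, changed by -1.26 ± 0.12 and PSAN, a subunit of photosystem I, by -1.21 ± 0.19 (SE, n = 4 arrays per group). RBCS2B fell by 0.83 ± 0.11, whereas RBCS1A differed by 0.02 ± 0.10 (adjusted p = 0.951), and whether probes tell these closely related genes apart was not examined. Over all genes 14 of 47 members fell and none rose, and 17 fell adjusted over the list alone. The median was -0.23 (camera adjusted p = 1.16e-06), with an adjusted p = 0.574 with an estimated correlation. The epidermis median beside it was -0.48. After cyclic loess the photosynthesis median was -0.12 and 8 members fell. The count was 7 without labelled-depleted replicate 2, 8 without wild type replicate 4, and 9 without wild type replicate 2 or labelled-depleted replicate 1 or 3.

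Cytosolic ribosomal protein genes had a median of -0.34. RPS6A changed by -0.97 ± 0.19 and RPS5B by -0.84 ± 0.18, both proteins of the small subunit (SE, n = 4 arrays per group). Over all genes 7 of 24 members fell, 11 adjusted over the list alone, and none rose. Without wild type replicate 1 or 2 or labelled-depleted replicate 1 the count over all genes was 4. The camera adjusted p was 0.000279, with an adjusted p = 0.695 with an estimated correlation. Fry did not call the list (adjusted p = 0.0638), and the epidermis median on the same arrays was -0.48.

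Among abscisic acid and drought response genes, decreases outnumbered increases. RD29A, a desiccation- and cold-responsive gene, changed by -2.22 ± 0.36, and RD20, a calcium-binding caleosin, by -1.55 ± 0.34 (SE, n = 4 arrays per group). The labelled-depleted mean of RD29A, 3.51, lay near the array median of 2.73, so the size of its fall is less certain. The transcription factor RD26 rose by 1.16 ± 0.21 and the chloroplast chaperone gene ERD1 by 0.91 ± 0.13. Over all genes 11 of 28 members fell and 3 rose, against 12 and 3 adjusted over the list alone. The median was -0.40 (camera adjusted p = 0.00238), with an adjusted p = 0.489 with an estimated correlation.

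Among auxin response genes, decreases also outnumbered increases. Beside IAA29 and SAUR21, the repressor IAA5 changed by -1.66 ± 0.17 and the auxin efflux carrier PIN7 by -1.52 ± 0.22, while IAA2 rose by 0.62 ± 0.18 (SE, n = 4 arrays per group). The lower group mean of IAA5, 2.29, lay below the array median of 2.73. Over all genes, and adjusted over the list alone, 9 of 21 members fell and 1 rose. The median was -0.38 (camera adjusted p = 0.00507), with an adjusted p = 0.695 with an estimated correlation. With fry the list was not called (adjusted p = 0.0638), and the epidermis markers had a median of -0.48. The auxin median was -0.24 without labelled-depleted replicate 2 and -0.24 without labelled-depleted replicate 3. The call of IAA2 was lost without any single array other than labelled-depleted replicate 1, at 0.46 to 0.67.

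Markers of the epidermis and cuticle were the only cell type list called. CER1, an enzyme of wax alkane synthesis, changed by -1.89 ± 0.32 and the epidermal homeodomain factor PDF2 by -0.84 ± 0.13, whereas CER3, its partner in alkane synthesis, rose by 0.75 ± 0.16 (SE, n = 4 arrays per group). Over all genes 6 of 13 members fell and 1 rose, against 8 and 1 adjusted over the list alone. The median was -0.48 (camera adjusted p = 0.00155), with an adjusted p = 0.489 with an estimated correlation.

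**Figure D2:**
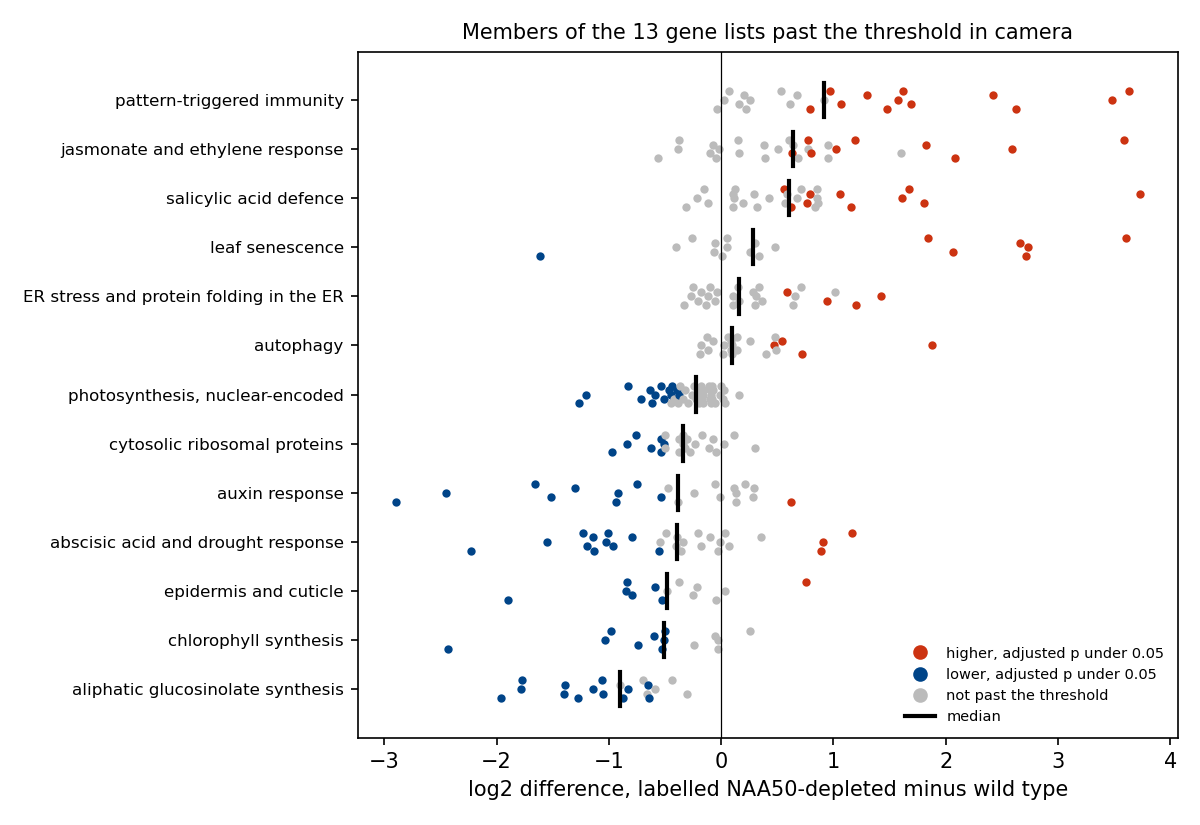
Log2 difference of each member (horizontal axis, labelled NAA50-depleted minus wild type) for the 13 gene lists past an adjusted p of 0.05 in camera (vertical axis), with red and blue points for members higher or lower past the threshold in limma, grey points for the others and a black line at the median. The medians run from -0.90 for aliphatic glucosinolate synthesis to 0.91 for pattern-triggered immunity.

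Cell wall expansion genes changed in both directions, and the list was not called in camera (median -0.46, adjusted p = 0.517). Beside XTH22, the xyloglucan-modifying gene XTH33 rose by 2.23 ± 0.25, and beside XTH31, the expansin EXPA3 fell by 1.80 ± 0.20 (SE, n = 4 arrays per group). The wild type mean of XTH33, 2.79, lay near the array median of 2.73, so the size of its rise is less certain. Over all genes 6 of 22 members rose and 9 fell, against 9 and 12 adjusted over the list alone. Of the circadian clock genes 5 of 21 rose and 3 fell, against 5 and 4 adjusted over the list alone (median 0.01, camera adjusted p = 0.706). The evening-phased repressors PRR5 and TOC1 rose by 1.95 ± 0.22 and 1.67 ± 0.22, while the morning-phased PRR9 and LNK1 changed by -2.13 ± 0.17 and -1.35 ± 0.11. CCA1 differed by 0.11 ± 0.20 (adjusted p = 0.794) and LHY by -0.33 ± 0.22 (adjusted p = 0.402).

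Genes of indolic glucosinolate and camalexin synthesis also changed both ways. MYB51 rose by 2.71 ± 0.36 and the methyltransferase IGMT1 by 2.00 ± 0.31, while MYB34 changed by -1.96 ± 0.32 and the lyase SUR1 by -0.74 ± 0.14 (SE, n = 4 arrays per group). Over all genes 2 of 14 members rose and 3 fell, against 3 and 4 adjusted over the list alone. The list median was -0.27, its mean 0.06 and its camera direction down (adjusted p = 0.887). The median was -0.48 without labelled-depleted replicate 3, -0.14 without labelled-depleted replicate 4, -0.17 without wild type replicate 1 and -0.16 after cyclic loess. Without labelled-depleted replicate 3 the count of members that fell was 5. For oxidative stress and detoxification 4 of 21 rose and 4 fell, against 4 and 5 adjusted over the list alone (median -0.19, camera adjusted p = 0.887). That median ran from -0.32 with the filter on dim loci to -0.02 without wild type replicate 2 or labelled-depleted replicate 1. The glutathione transferase GSTF7 rose by 2.79 ± 0.30 and the zinc finger factor ZAT12 by 2.31 ± 0.50, while the iron superoxide dismutase FSD1 changed by -2.42 ± 0.47 and the ferritin FER1 by -1.68 ± 0.33. The lower group means of IGMT1 (1.29), MYB34 (2.30), ZAT12 (2.52) and FER1 (2.42) lay below the array median of 2.73, so the sizes of these changes are less certain. The wild type mean of GSTF7 (3.24) lay near that median, with the same limit.

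In flavonoid and anthocyanin synthesis the regulator MYB75 changed by -1.96 ± 0.26 and chalcone synthase, CHS, by -1.96 ± 0.28 (SE, n = 4 arrays per group). The labelled-depleted mean of MYB75, 3.69, lay near the array median of 2.73, so the size of its fall is less certain. Of 22 members 4 fell over all genes and 5 adjusted over the list alone, and none rose (median -0.19, camera adjusted p = 0.145). Without labelled-depleted replicate 1 the median was -0.38 (camera adjusted p = 0.0511) and 1 member rose over all genes. Without wild type replicate 1 it was -0.13. In sulfur assimilation and sulfur deficiency 6 of 26 members rose and 3 fell over all genes, against 9 and 4 adjusted over the list alone. SDI1, a sulfur deficiency gene, rose by 2.14 ± 0.33 and the vacuolar sulfate transporter SULTR4;2 by 0.96 ± 0.28, while sulfite reductase, SIR, changed by -1.11 ± 0.20 and the cysteine synthase OASA1 by -0.53 ± 0.15. The sulfur list, with a median of 0.12, missed the threshold in camera (adjusted p = 0.145) and passed it without wild type replicate 4 (0.21) or labelled-depleted replicate 2 (0.19). Its median was 0.22 after cyclic loess, 0.19 without labelled-depleted replicate 4 and 0.07 without labelled-depleted replicate 3, none of them past the threshold. The count of members that fell was 1 after cyclic loess and without wild type replicate 4 or labelled-depleted replicate 2. The call of SULTR4;2 was lost without wild type replicate 1 or 2 or labelled-depleted replicate 1, 3 or 4, at 0.73 to 1.01, and with array weights, at 0.88. That of OASA1 was lost without wild type replicate 1, 3 or 4 or labelled-depleted replicate 2 or 4, at -0.53 to -0.42, and after cyclic loess, at -0.40.

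Among aquaporins TIP2;1 rose by 0.93 ± 0.26, while TIP2;2 changed by -0.85 ± 0.19 and PIP2;6 by -0.79 ± 0.13 (SE, n = 4 arrays per group). Of 15 members 1 rose and 3 fell over all genes, against 3 and 6 adjusted over the list alone (median -0.21, camera adjusted p = 0.464). The median was -0.03 without wild type replicate 1, -0.04 without labelled-depleted replicate 1 and -0.08 after cyclic loess. The call of TIP2;1 was lost without wild type replicate 2, 3 or 4 or labelled-depleted replicate 2 or 4, at 0.77 to 0.92, and, at 0.93, with a trended and robust variance model or the replicate number as a block. HSFB1, a heat shock factor, rose by 0.75 ± 0.16 as 1 of 18 heat shock members, in both counts. The heat shock list had a median of -0.01, a mean of 0.004 and the camera direction up (adjusted p = 0.887). TSO2, a ribonucleotide reductase subunit, rose by 0.86 ± 0.24 as 1 of 29 genes of the cell cycle and DNA replication, and none passed adjusted over the list alone (median -0.01, camera adjusted p = 0.887). The call of TSO2 was lost without wild type replicate 1, 2 or 3 or labelled-depleted replicate 1, at 0.82 to 0.88. None of the 31 genes of the 26S proteasome passed over all genes or adjusted over the list alone (median -0.05, camera adjusted p = 0.919), and PAF1 differed most, by 0.35 ± 0.13 (adjusted p = 0.110).

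The other cell type lists were not called in camera. Of 11 guard cell and stomatal markers the kinase gene OST1 rose by 0.63 ± 0.15, and the channel genes KAT1 and SLAC1 changed by -0.92 ± 0.21 and -0.60 ± 0.15 (SE, n = 4 arrays per group). Adjusted over the list alone 1 rose and 3 fell (median -0.29, camera adjusted p = 0.399), and without wild type replicate 1 the median was -0.07. The call of SLAC1 was lost without wild type replicate 1 or 4 or labelled-depleted replicate 1 or 2, at -0.59 to -0.49. The phloem sugar transporter SWEET12 rose by 0.58 ± 0.16 as 1 of 9 phloem markers in both counts (median -0.01, mean 0.002, camera direction up, adjusted p = 0.887), and its call was lost without any single array other than labelled-depleted replicate 3, at 0.44 to 0.62. SPL4, a regulator of flowering, rose by 0.54 ± 0.16 as 1 of 14 flowering markers, with none adjusted over the list alone, at group means of 1.59 and 2.14 that lie below the array median of 2.73. The flowering list had a median of -0.03, a mean of -0.0002 and the camera direction up (adjusted p = 0.887), and the call of SPL4 was lost without any single array other than labelled-depleted replicate 4, at 0.37 to 0.60, and with the replicate number as a block, at 0.54. No marker passed over all genes or adjusted over the list alone among 9 of the root (median -0.07), 10 of the trichome (-0.05), 14 of the xylem (-0.10), 9 of the meristem (-0.07) or 12 of the seed (-0.12), with camera adjusted p-values of 0.887, 0.887, 0.887, 0.905 and 0.517. The members of these lists that differed most were PYK10 (0.34 ± 0.23), TRY (-0.48 ± 0.20), CESA7 (-0.37 ± 0.16), ANT (-0.28 ± 0.19) and CRU3 (-0.34 ± 0.12), at adjusted p-values of 0.399, 0.159, 0.179, 0.404 and 0.0898. The value of PYK10 was 0.11 without labelled-depleted replicate 3 and 0.52 without labelled-depleted replicate 2, that of CESA7 -0.20 without wild type replicate 2, and those of TRY and ANT -0.30 and -0.14 without wild type replicate 1. Both group means of SWEET12, PYK10, CESA7 and ANT lay below the array median.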

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

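The tests of exchanged labels, of an insertion at the NAA50 locus and of the time of harvest were chosen only after the results they bear on were seen. The 4042 genes that differed between the groups were set against the other splits of the 8 arrays into 4 and 4. Of the 35 splits only 1, the real one, gave as many, and the highest of the others gave 0. A share of 1 in 35 is the smallest this comparison can give, so it does not exclude chance. The other splits carry the real difference as spread within their groups, which lowers their counts.

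In 9 of 178 groups of 4 arrays of a named gene, 1 array lay far from the other 3, where chance gives 8.9. DIN10 read 9.23 on labelled-depleted replicate 4 against 8.75 on the nearest array, and XTH22 read 9.23 on labelled-depleted replicate 3 against 8.96. RBCS1B read 10.12 on wild type replicate 1 against 9.89, and BZIP60 read 5.32 there against 5.83. PRR5 read 6.40 on labelled-depleted replicate 3 against 5.75, and TSO2 read 4.26 on wild type replicate 4 against 3.88. SPL4 read 1.645 on wild type replicate 2 against 1.58 and 2.64 on labelled-depleted replicate 1 against 2.03. GNAT3 read 5.51 on wild type replicate 1 against 4.67.

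NAA50 was higher by 5.83 on the arrays labelled depleted, against the label if the label refers to transcript. If the group labels were exchanged, all 8 arrays would lie on the side opposite to their label, and 8 of 8 did, but a true rise gives the same picture, so these cannot be told apart, and an exchange would turn every direction in the text. If an insertion at the NAA50 locus also drove its neighbours, a flanking locus would rise by more than is usual: AT5G11350 rose by 1.02 ± 0.17 and AT5G11330 differed by -0.33 ± 0.11 (adjusted p = 0.0762), while 6.45% of loci had a flanking locus that rose as much, which leaves this open because it missed the 5% the test asked for without meeting its lower bound. Transcript made by a construct that the probes read could not be tested with 1 value per locus. A rise of the transcript that belongs to the genotype stays open and untested.

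Immunity genes such as WRKY22 and the touch gene XTH22 rose on the arrays labelled depleted, and handling or wounding before freezing was weighed as a technical cause. Of 8 rapid touch and wound genes whose values had not been seen, 6 were higher past an adjusted p of 0.05 in limma, the number set beforehand for this explanation. Among all genes 6.95% were higher, and among genes with a mean above 4 it was 13.0%. Handling may therefore contribute, but the same genes respond to immune signalling, so the test does not separate handling from an effect of the genotype, which stays open and untested.

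Dark-induced genes such as DIN10 rose while genes of photosynthesis and chlorophyll synthesis such as RBCS1B and HEMA1 fell. Under carbon starvation at least 6 of 8 starvation genes not seen before would be higher, and 2 or fewer if not, and 5 were, which decides neither way. Under a harvest at another time of day CCA1 and LHY would fall while TOC1, PRR5 and GI rise, or the reverse. TOC1 and PRR5 rose while GI fell by 0.81 ± 0.22, so that pattern was not met. The test did not use the other clock genes called. Of these ELF3 (1.00 ± 0.13), RVE1 (1.08 ± 0.24) and LUX (0.47 ± 0.13) rose, while PRR9 (-2.13 ± 0.17) and LNK1 (-1.35 ± 0.11) fell. The group means of LUX, 1.53 and 2.00, lay below the array median of 2.73. The mean of CCA1 and LHY differed by -0.11, with a 95% interval from -0.70 to 0.49 that is too wide to exclude a displacement. Both explanations may apply and cannot be told apart from each other here, since starvation moves some of the same genes. The labels give the same harvest time for all samples. An effect of the genotype stays open and untested.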

How the results depend on the processing

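All alternatives named here were fixed in advance. Genes changed numbered 3826 after cyclic loess (3493 of them among the 4042), 4187 of 21048 loci with the filter on dim loci, 4074 with the trended and robust model, 4124 with array weights and 3254 to 3675 with 1 array left out. Quantile normalization and median centring changed nothing, because the arrays already shared 1 distribution. At an adjusted p of 0.01 the count was 2238 (1228 higher, 1010 lower) and with treat 1913 (1115 higher, 798 lower), both by construction stricter. NAA50 stayed between 5.72 and 5.95 in all fits. With the estimated correlation the calls of the 13 lists were lost at unchanged medians. Their estimates ran from 0.039 (senescence) to 0.593 (jasmonate and ethylene), above the preset 0.01 on which the camera calls rest. How far this alone accounts for the losses was not tested. The medians were 0.91 (pattern-triggered immunity), -0.90 (aliphatic glucosinolates), -0.23 (photosynthesis), 0.60 (salicylic acid), 0.64 (jasmonate and ethylene), -0.51 (chlorophyll), -0.34 (ribosomal proteins), 0.28 (senescence), -0.48 (epidermis), -0.40 (abscisic acid), -0.38 (auxin), 0.093 (autophagy) and 0.16 (ER). With fry 4 of these were lost, at 0.64 for jasmonate and ethylene (adjusted p = 0.187), -0.34 for ribosomal proteins (0.0638), -0.38 for auxin (0.0638) and 0.16 for ER (0.416), and the N-terminal acetyltransferases (-0.045) were gained at 0.0126; the cause was not tested. The ER list reversed to -0.079 (adjusted p = 0.916) without labelled-depleted replicate 1 and ranged from -0.079 to 0.306 with 1 array left out. The sulfur list ranged from 0.071 to 0.209 and was gained without wild type replicate 4 (0.21, adjusted p = 0.0384) and without labelled-depleted replicate 2 (0.19, adjusted p = 0.0414); the cause was not tested. Of 1320 alternative values of the 88 named genes other than NAA50, 1256 kept their side of the threshold, 61 lost a call (10 genes), 3 gained one (HYPK) and 0 called values reversed, while NAA10 and NAA15, which were not called, each changed sign in 1 alternative. With the replicate number as a block 3545 genes were called, 3373 of them shared, and no list call changed, while the calls of SPL4 (0.54) and TIP2;1 (0.93) were lost. The numbers share no deviations: arrays of the same number correlated at -0.049, 0.023, -0.033 and 0.039 in their deviations from the group means, and 2 of 8 arrays correlated best with their own number. The means of probe sets and the test of all probe sets were not run, since the table has 1 value per locus. Signal over background was not measured here and may be low for loci at the dim end of the arrays, which limits calls there.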

Other observations

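The gene groups in this part were put together after some of their values had been seen, and the prediction on iron genes was tested on members whose values had not been. Genes known to rise in darkness or carbon starvation were mostly higher on the arrays labelled NAA50-depleted, with 19 of 29 measured members past an adjusted p of 0.05 in limma, none lower and a median of 1.61. Beside BT2 and DIN10, the trehalose-phosphate synthase family gene TPS9 rose by 2.73 ± 0.15 on the log2 scale (SE, n = 4 arrays per group), SEN1 by 2.72 ± 0.32 and ASN1, an asparagine synthetase, by 2.06 ± 0.21. SEN1 and ASN1 are also members of the leaf senescence list, so the observations on that list and on this group overlap. BZIP1, a transcription factor of the low-energy response, rose by 1.85 ± 0.13 and the beta-galactosidase BGAL4 by 2.35 ± 0.22, from wild type means of 2.67 and 2.48 that lay below the array median of 2.73. DIN9 differed by -0.18 ± 0.20 (adjusted p = 0.663) and DIN2 by 0.24 ± 0.14 (adjusted p = 0.330). Rapid touch and wound genes were higher in 10 of 14 cases and lower in none, with a median of 2.58. The calmodulin-like TCH3 rose by 3.00 ± 0.15, WRKY40 by 3.45 ± 0.35, the zinc finger factor STZ by 3.27 ± 0.34 and the ubiquitin ligase CMPG1 by 2.88 ± 0.17.

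The paralogous transcription factors GLK1 (listed as GPRI1) and GLK2, which activate chlorophyll and photosynthesis genes, changed by -2.05 ± 0.17 and -1.23 ± 0.12 (SE, n = 4 arrays per group), with adjusted p-values in limma of 2.24e-05 for GPRI1 and 7.00e-05 for GLK2. Of 92 mitochondrial loci 4 were higher and none lower, with a median of 0.20, and of 14 plastid loci 0 changed, with a median of -0.02. Among all loci 6.95% were higher and 7.58% lower, so the mitochondrial count shows no excess of increases.

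Iron genes past the threshold moved in the direction of iron deficiency with 1 exception, NAS1, while other members did not pass. The transcription factor gene BHLH100 rose by 3.37 ± 0.71, BHLH101 by 2.23 ± 0.51 and the ferric reductase FRO3 by 1.74 ± 0.32 (SE, n = 4 arrays per group), whereas the nicotianamine synthase NAS1 fell by 2.01 ± 0.17. Of 17 genes known to rise in iron deficiency 7 were higher and 1 lower past an adjusted p of 0.05 in limma, and of 4 known to fall 3 were lower. Among the rising genes not called, FRO2 (group means 1.84 and 2.04), IRT1 (1.28 and 1.04) and MTPA2 (1.73 and 1.59) lay below the array median of 2.73. Their lack of a call is therefore less certain. The hypothesis of an iron deficiency response predicted that at least 5 of 7 genes not seen before would move in its direction, and 2 or fewer if it were wrong. It was 3 of 7, BTS, FRO3 and FER4, so the test leaves the hypothesis open, and such a response may or may not be present. FER4 passed narrowly (adjusted p = 0.0478 in limma), at group means of 2.22 and 1.73 that lay below the array median of 2.73. Its call, and so the count, is less certain.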
